A study of Mus musculus with 6 samples.

How the data were processed

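Whole snap-frozen kidneys of male mice were profiled by RNA sequencing, 6 samples, 3 control kidneys (Pkd1 floxed, Cre transgene, no Pax8-driven activator) and 3 Pkd1 KO kidneys (the same with the activator). Per the labels' protocols, RNA was extracted with a column kit, poly-A RNA was purified and fragmented, and complementary DNA was made with random primers. RNA quality was read by photometer per the labels, and no measure of RNA integrity is given in the sources used here. Groups and sample numbers were taken from the sample titles, and doxycycline dose, days and age from the labels. Which Pkd1 exons were floxed is not given in the sources used here.

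The deposited values were raw read counts per gene, 1 table per sequencing run and 7 tables in all, with no normalization by the authors. The submitters' processing notes name cutadapt 4.0, FastQC 0.11.8, STAR 2.6.1e and the mouse genome build GRCm39. The layout is that of STAR's gene counts, with 1 column that ignores strand and 2 that count each strand, and the gene annotation behind the counts is not given in the sources used here. The first strand column held 49.1% to 50.0% of the reads of both strand columns, so the column that ignores strand was used, and reads of overlapping genes on opposite strands could not be separated. Each table opened with 4 lines that name no gene (unmapped, multimapped, outside genes, ambiguous). They held 22.9%, 23.5% and 23.8% of reads in the controls and 25.3%, 26.3% and 25.6% in the Pkd1 KO libraries, and stayed out of library sizes and tests. STAR counts a read only where it maps to 1 place, which lowers genes with close copies.

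Control 1 had 2 runs, which were summed and counted as 1 replicate. A chi-square comparison of counts gave 3.59 per gene between these runs, 75.6 to 257 between controls and 26.1 to 32.7 between Pkd1 KO libraries, so no libraries were merged as copies. Gene counts per library were 45020173 to 62983791. The names of the deposited tables carried 1 sequencing project for all 3 controls and another for all 3 Pkd1 KO libraries, so no fit with project as a term could be made. Gene symbols, biotypes, exon lengths (union of exons) and GC content (longest transcript) came from GENCODE M21, which describes an older build than GRCm39. It was joined by gene identifier, gave a symbol to 52073 of 56923 identifiers, and no coordinates from it are printed. Gene names such as Hist1h1e are those of that annotation.

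The test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on Pkd1 KO against control, with filterByExpr, TMM normalization and Benjamini-Hochberg adjustment at 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 21.4%. CPM values are gene counts scaled by the TMM library size, and group values are means ± SD. Gene lists, 52 in all with 1056 entries of which 2 matched no identifier, were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2) where at least 5 members were tested, beside camera with an estimated correlation and fry. Lists overlap in some genes, such as Ccl2, Col3a1, Atf3, Sdha and Cfd. The design of each test, the lists and the alternatives without further remark were fixed before the data were examined.

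The rule for named genes, fixed then, took Pkd1 and Pkd2, all tested inflammasome members, and the 10 highest and 10 lowest protein-coding genes past the threshold with a mean log2 CPM of at least 2 and groups apart. In each list it took up to 4 called members with the largest change in the main direction and up to 2 in the other (mean log2 CPM of at least 0), or the 2 most abundant where none was called. The text names fewer per list, mostly 2 in the main direction and 1 in the other, a narrowing made after the values were seen. S100a8, S100a9, Tnni2, mt-Nd6 and the genes that open the other observations were also chosen after their values were seen. Results of some genes that the rule took are not reported here.

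Because fold changes followed GC content and length, a second fit added offsets. For each library the log2 CPM of a gene was first taken relative to its mean over all libraries of both groups. A loess surface (span 0.3) of these values against GC content and log2 exon length entered the same edgeR test as an offset. It covered the 17785 genes (97.3%) with both properties. A list-wide or tissue-wide change in long or GC-rich genes would also be removed by it.

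The scripts were tested on simulated counts drawn for 17929 genes from the real means and library sizes, 3 against 3. Of 50 genes changed per size, 6 were recovered at 1.5-fold, 39 at 2-fold, 50 at 3-fold and 49 at 4-fold, and 9 of 153 calls had not been changed. With a simulated trend on GC content and length, 1254 unchanged genes were called without offsets and 5 with them. The simulation changed a far smaller share of genes than was called in the data. These counts therefore check the scripts and do not measure power or error in the real comparison. The alternatives tried were DESeq2 size factors, upper-quartile scaling, library size alone, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 samples, each library left out, the sample number as a block, offsets with and without that block, each strand column, each run of control 1 alone, counts thinned to the shallowest library and no mitochondrial genes. A finer loess and offsets without control 2 were added after seeing the data.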

Results

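RNA sequencing measured messenger RNA in 6 whole kidneys of male mice, 3 in each of 2 groups. Pkd1 encodes polycystin-1, the membrane protein most often mutated in autosomal dominant polycystic kidney disease. In the knockout group (Pkd1 KO) both Pkd1 alleles were floxed and a Pax8-driven, doxycycline-dependent Cre recombinase could delete them in tubule cells. Control mice had the floxed alleles and the Cre transgene without the Pax8-driven activator. All mice drank doxycycline at 2 mg/ml with 5% sucrose from postnatal day 28 to day 42, for 14 days, and kidneys were taken at 10 weeks. The comparison asks which transcripts differ between kidneys with induced Pkd1 deletion and control kidneys, described as non-cystic by the submitters, with the inflammasome, the protein complex that activates caspase-1 and matures interleukin-1β and interleukin-18, as the study's stated interest.

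The control libraries held 50456629, 55548316 and 45020173 gene counts and the Pkd1 KO libraries 51966474, 62983791 and 61614713. Control 1 was sequenced in 2 runs, of 39142952 and 11313677 gene counts, which were summed. The first principal component held 70.4% of the variance of log2 CPM and separated the groups, with the controls at −58.1, −92.7 and −24.2 and the Pkd1 KO libraries at 52.4, 66.4 and 56.1. The 3 control libraries came from 1 sequencing project and the 3 Pkd1 KO libraries from another, and 0 of the 2 projects held both groups, so project and genotype cannot be told apart in any value below. The labels name the samples as separate kidneys without saying more of the animals, so p-values of single genes measure the spread between these samples. Camera's p-values instead compare the genes of a list with the other genes. With the preset correlation of 0.01 they take list members as nearly independent.

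Pkd1 (ENSMUSG00000032855) was counted in every library. The controls had 30.01, 46.4 and 23.6 CPM and the Pkd1 KO libraries 8.77, 9.003 and 10.01 CPM. The means were 33.3 ± 11.8 and 9.26 ± 0.66 CPM (SD, n = 3 each), a log2 fold change of −1.85 ± 0.24 (SE) with an adjusted p of 0.00234 in edgeR's quasi-likelihood test. The count covers the whole gene, including any part outside the floxed exons, and cells in which Pax8 is not active. Pkd1 is a long, GC-rich gene (17415 exonic bases, 56.8% GC), and such genes were lower in the Pkd1 KO libraries as a class. Among the 200 genes nearest to Pkd1 in length, GC content and expression the median log2 fold change was −1.32, and 25 of them fell further than Pkd1. With offsets for GC content and length the Pkd1 value was −0.34 ± 0.13 and its call ended (adjusted p = 0.0644). The call stayed in edgeR's test with a finer loess (−0.46, adjusted p = 0.016) and with the offsets without control 2 (−0.45, adjusted p = 0.0161). Both settings were added after seeing the data. Pkd2, whose product polycystin-2 pairs with polycystin-1, stood at −0.59 ± 0.24 (adjusted p = 0.0711). Its adjusted p was 0.00318 at −0.86 without control 3 and 0.0383 in DESeq2's own test, and its value turned to 0.043 with the offsets (adjusted p = 0.844, the highest of its alternatives).

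Of 18273 genes tested, 8579 (46.9%) changed, 4148 of them higher and 4431 lower in Pkd1 KO kidneys, and 4045 changed at least 2-fold (2113 higher, 1932 lower). The 3 values of 1 group lay above the 3 of the other for 11178 genes (61.2%). For a single gene in interchangeable libraries the chance is 10%. Genes are not independent of each other, so the distance between these shares is not a test. Upper-quartile scaling shifted the median log2 fold change of all genes from 0.03 to 0.19 and the higher share of calls from 48.4% to 60.5%. Leaving out single libraries gave from 5071 calls (without KO 2) to 10318 (without control 3), and 6097, 8517, 6213 and 5871 without control 1, control 2, KO 1 and KO 3. Genes called higher numbered 2635 without control 1 and 2340 without KO 2, where 2731 were lower.

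Fold changes followed gene structure. The median log2 fold change went from 0.65 in the shortest eighth of genes to −0.51 in the longest, and from 0.56 in the eighth with the lowest GC content to −0.60 in that with the highest. After fitting each library's trend on GC content and length as an offset, the medians of all 16 eighths lay between −0.03 and 0.06. The trend was fitted on the same genes, so medians near 0 follow from the fit. They do not show whether a bias or a change in the kidneys was removed. This offset fit covered 17785 genes, called 6128 (3043 higher, 3085 lower) and counted 1803 with at least a 2-fold change. Both fits called 4389 genes in one direction (2219 higher, 2170 lower) and 60 in opposite directions. Below, the parentheses after a gene hold its log2 fold change, Pkd1 KO minus control, ± SE (n = 3 each), then its value in the offset fit. An adjusted p after the offset value is that of the offset fit, given where the edgeR quasi-likelihood test did not pass 0.05 there. Genes not called without the offsets carry the adjusted p of that fit and no offset value. Counts of called list members are to be read against all 18273 tested genes, of which 46.9% were called, 4148 higher and 4431 lower. A list with shares near these does not stand out from the other genes.

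**Figure D1:**
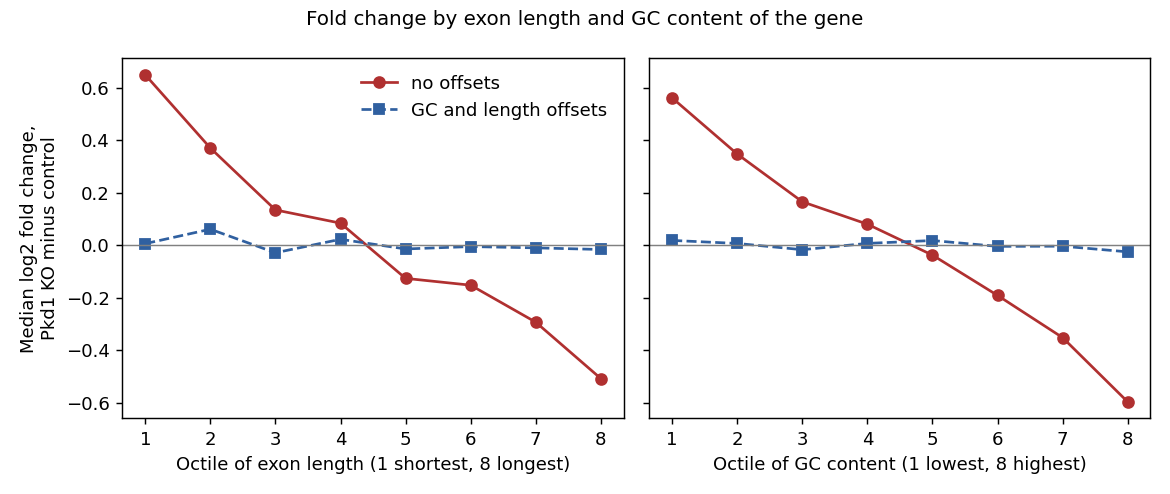
Median log2 fold change (Pkd1 KO minus control) of tested genes in 8 equal groups by exon length (left) and by GC content (right), without offsets (circles) and with GC and length offsets (squares). Without offsets the medians fell from 0.65 to −0.51 with length and from 0.56 to −0.60 with GC content.

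Among protein-coding genes with a mean log2 CPM of at least 2 and groups that did not overlap, the 10 largest increases included a marker of proximal tubule injury and genes of mitosis. Kidney injury molecule 1, Havcr1 (3.61 ± 0.77, offset fit 2.85), led the list, at 52.1 ± 32 CPM against 4.23 ± 4.5. It was followed by the mitotic kinases Pbk (3.61 ± 0.33, offset fit 2.85) and Cdk1 (3.45 ± 0.33, offset fit 3.48). Also among the 10 were the kinetochore and spindle genes Nuf2 (3.38 ± 0.27, offset fit 3.07), Knstrn (3.10 ± 0.29, offset fit 3.09) and Hmmr (3.06 ± 0.29, offset fit 2.69), and the PCNA-associated factor Pclaf (2.98 ± 0.32, offset fit 2.64). The remaining ones, with sizes in between, were Trdn (3.40 ± 0.27, offset fit 2.95), a sarcoplasmic reticulum protein, the prostaglandin D synthase Ptgds (3.27 ± 0.34, offset fit 3.22) and Wfdc17 (3.07 ± 0.40, offset fit 2.09). The 10 lowest among them were led by Lad1 (−3.22 ± 0.24, offset fit −2.65), an anchoring-filament protein of basement membranes, Myh14 (−2.86 ± 0.55, offset fit −1.40) and Evpl (−2.63 ± 0.61, offset fit −1.20). They included the proton pump subunit Atp4a (−2.52 ± 0.21, offset fit −2.04) and the amino acid exchanger Slc7a8 (−2.48 ± 0.49, offset fit −2.001). Others among them were Tnrc18 (−2.47 ± 0.50, offset fit −0.64, adjusted p = 0.0604), Dst (−2.47 ± 0.63, offset fit −0.83, adjusted p = 0.0545), Cep250 (−2.44 ± 0.64, offset fit −0.94, adjusted p = 0.106) and the mechanosensitive channel Piezo1 (−2.43 ± 0.35, offset fit −0.99). Much of the size of the low end rested on control 2: leaving it out moved the log2 fold change from −2.86 to −1.88 for Myh14, −2.63 to −1.52 for Evpl, −2.47 to −1.61 for Tnrc18, −2.47 to −1.22 for Dst and −2.44 to −1.21 for Cep250. The calls lost in edgeR's test with another library left out, with the adjusted p, were those of Dst (0.0557 without KO 1) and Cep250 (0.0594 without KO 1 and 0.0534 without KO 2).

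Most tested genes of the inflammasome list, which also holds cytokine, receptor and inhibitor genes, were called higher in Pkd1 KO kidneys. Of 26 tested members, 15 rose, 1 fell and 10 were not called (15 and 1 adjusted over the list alone), with a median of 0.91. Inflammatory caspase genes rose, Casp4 (2.19 ± 0.29, offset fit 1.37), the sensor of cytosolic lipopolysaccharide, from 1.32 ± 0.42 to 5.98 ± 1.4 CPM (SD) and Casp1 (2.06 ± 0.33, offset fit 1.19) from 1.20 ± 0.48 to 5.00 ± 1.4. The adaptor Pycard (1.06 ± 0.18, offset fit 0.78), the pore-forming Gsdmd (0.77 ± 0.18, offset fit 0.80) and Gsdme (0.52 ± 0.13, offset fit 0.38), and the cytokines Il1b (1.46 ± 0.33, offset fit 0.86, adjusted p = 0.0661) and Il18 (1.35 ± 0.20, offset fit 0.51, adjusted p = 0.0979) rose as well. So did the interleukin-1 receptor antagonist Il1rn (2.75 ± 0.78, offset fit 2.38) and the interleukin-18 receptor genes Il18r1 (1.77 ± 0.44, offset fit 1.501) and Il18rap (1.86 ± 0.47, offset fit 1.87). Il1rn was near the floor of the counts, at 0.104 ± 0.090 CPM in controls and 0.679 ± 0.34 in Pkd1 KO kidneys. Il18rap was low too, at 0.427 ± 0.33 and 1.53 ± 0.21 CPM. Among sensors, Aim2 (1.20 ± 0.29, offset fit 0.67, adjusted p = 0.0758), Naip1 (1.79 ± 0.32, offset fit 1.75), Naip2 (1.47 ± 0.27, offset fit 1.41) and Naip5 (1.15 ± 0.22, offset fit 1.04) rose. The Naip genes are close copies of each other, so their separate counts are uncertain. Naip1 was also low, at 0.263 ± 0.044 CPM in controls and 0.911 ± 0.13 in Pkd1 KO kidneys. Nek7 (0.61 ± 0.16, offset fit 0.30, adjusted p = 0.114), a partner of NLRP3, rose, while Nlrp6 (−0.80 ± 0.17, offset fit −0.23, adjusted p = 0.175), an epithelial sensor, fell. Nlrp3 itself was low and not called, at 0.722 ± 0.24 CPM in controls and 0.577 ± 0.14 CPM in Pkd1 KO kidneys (−0.32 ± 0.37, adjusted p = 0.504). The other uncalled members were Nlrp1a (1.05 ± 0.51, adjusted p = 0.118), Nlrp1b (0.27 ± 0.29, adjusted p = 0.460), Nlrc4 (−0.075 ± 0.28, adjusted p = 0.842) and Naip6 (−0.40 ± 0.35, adjusted p = 0.365) among the sensors. They also included Il1r1 (0.36 ± 0.15, adjusted p = 0.0798), Il1rap (0.33 ± 0.17, adjusted p = 0.134), Il18bp (0.35 ± 0.18, adjusted p = 0.142), Txnip (0.13 ± 0.24, adjusted p = 0.681) and P2rx7 (0.070 ± 0.21, adjusted p = 0.798). Upper-quartile scaling called Il1r1 (0.53, adjusted p = 0.0255) and Il1rap (0.49, adjusted p = 0.0315).

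Camera ranked the inflammasome list above other genes (adjusted p = 0.000719, adjusted p = 0.617 with an estimated correlation). With the offsets 11 members rose (camera adjusted p = 0.000189). Members that lost their call with a library left out, with the adjusted p, were Nek7 (0.0566 without KO 1 and 0.0574 without KO 2), Aim2 (0.0546 without KO 2), Gsdme (0.0567 without KO 2), Il1rn (0.0675 without KO 2 and 0.0737 without KO 3) and Il18rap (0.0512 without KO 2).

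**Figure D2:**
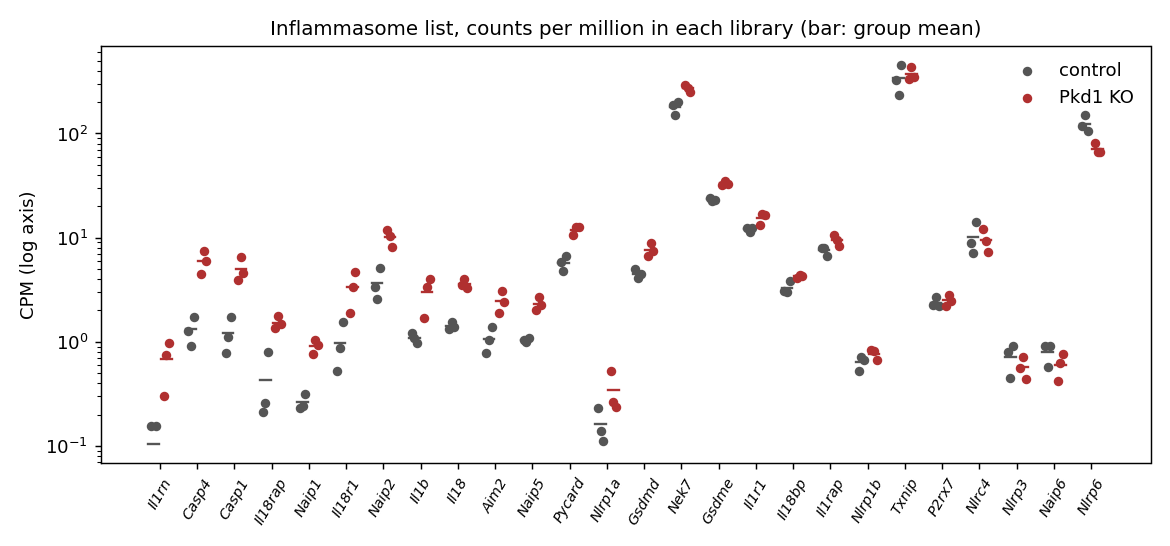
CPM (log axis) of the 26 tested inflammasome genes in each of the 3 control and 3 Pkd1 KO libraries, ordered by fold change, with a bar at each group's mean. For Casp4 and Casp1 the Pkd1 KO libraries lie above all controls, for Nlrp3 the groups overlap, and an Il1rn value of 0 in 1 control library is not drawn.

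Chemokine genes rose, such as Ccl8 (3.29 ± 0.50, offset fit 2.45), Cxcl1 (3.10 ± 0.49, offset fit 2.43), Ccl9 (2.97 ± 0.53, offset fit 2.36) and Ccl2 (2.81 ± 0.47, offset fit 2.01), all attractants of monocytes or neutrophils. Of 33 tested cytokines and chemokines, 20 rose and 2 fell (24 and 3 adjusted over the list alone), the latter being Cx3cl1 (−0.94 ± 0.15, offset fit −0.34, adjusted p = 0.120) and Tgfb1 (−0.66 ± 0.16, offset fit −0.25, adjusted p = 0.209). Camera gave an adjusted p of 0.000302 (adjusted p = 0.617 with an estimated correlation), and 14 members rose in the offset fit (camera adjusted p = 0.000169). Macrophage genes rose too, 17 of 26, with 2 lower (17 and 2 adjusted over the list alone). Examples were the β-glucan receptor Clec7a (2.89 ± 0.26, offset fit 2.10), lysozyme Lyz2 (2.70 ± 0.35, offset fit 2.13) and the scavenger receptor Msr1 (2.58 ± 0.33, offset fit 2.01). The growth factor receptor Csf1r (−1.01 ± 0.17, offset fit −0.33) and the efferocytosis receptor Mertk (−0.38 ± 0.13, offset fit −0.41) fell. The macrophage list had a camera adjusted p of 0.000133 (adjusted p = 0.617 with an estimated correlation) and 7.43e-05 with the offsets, where 16 members rose. Calls of this paragraph lost with a library left out, with the adjusted p, were those of Tgfb1 (0.0596 without KO 2) and Mertk (0.0818 without control 1, 0.142 without KO 1, 0.0597 without KO 2 and 0.170 without KO 3). Cytokine decreases thereby numbered 1 without KO 2, and macrophage decreases 1 without control 1, KO 1, KO 2 or KO 3.

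T and NK cell genes numbered 11 higher and 1 lower of 21 (12 and 1 adjusted over the list alone), among them Cd3d (2.08 ± 0.39, offset fit 1.70) and Nkg7 (1.5003 ± 0.31, offset fit 0.98), with Il2rb (−0.86 ± 0.30, offset fit −0.43, adjusted p = 0.260) the one that fell. Camera on the T and NK cell list gave an adjusted p of 0.00183 (adjusted p = 0.617 with an estimated correlation). The offset fit called 5 of them higher (camera adjusted p = 0.00473), and the count of increases was 7 without control 1, control 3 or KO 1, 4 without KO 2 and 6 without KO 3. B and plasma cell genes gave 6 increases among 14 (6 adjusted over the list alone), such as Jchain (2.47 ± 0.40, offset fit 1.54) and Igkc (1.93 ± 0.48, offset fit 1.06, adjusted p = 0.102), and 2 with the offsets, with no camera call (adjusted p = 0.0932, but 0.0243 without control 2 and 0.0388 without KO 3). The increases numbered 3 without control 1 or KO 1, and 1 gene was lower without control 2. In the dendritic cell list 4 of 10 rose (4 adjusted over the list alone), among them Cd209a (1.75 ± 0.33, offset fit 1.04) and Clec10a (1.49 ± 0.41, offset fit 1.38). Its camera call (adjusted p = 0.0492, adjusted p = 0.617 with an estimated correlation) was lost in some left-out fits (0.0735 without control 2, 0.0819 without control 3 and 0.0748 without KO 2), and the count was 2 without control 1 and 1 without KO 2. Of 5 tested neutrophil genes, S100a9 (1.74 ± 0.50, offset fit 0.80, adjusted p = 0.225) and S100a8 (1.48 ± 0.54, offset fit 0.63, adjusted p = 0.337) rose, both named after their values were seen (1 adjusted over the list alone). Both lay below the mean log2 CPM of 0 that the rule for named list members required. The most abundant members were Csf3r (−0.72 ± 0.32, adjusted p = 0.0936) and Mmp9 (0.27 ± 0.33, adjusted p = 0.523) (camera adjusted p = 0.854). Gene-level calls lost with a library left out, with the adjusted p, were those of Il2rb (0.124 without control 1, 0.0768 without control 2, 0.121 without KO 1, 0.0863 without KO 2 and 0.126 without KO 3), Igkc (0.0511 without control 1), Clec10a (0.0569 without control 1 and 0.0735 without KO 2), S100a9 (0.0713 without control 1 and 0.103 without KO 3) and S100a8 (0.156 without control 1, 0.0998 without control 2, 0.0710 without KO 1, 0.112 without KO 2 and 0.174 without KO 3). Neutrophil increases numbered 0 without control 1 or KO 3 and 1 without control 2, KO 1 or KO 2. Leaving out KO 1 moved the log2 fold change from 1.93 to 1.15 for Igkc.

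Interferon-response genes rose in 17 of 35 cases and fell in 2 (17 and 2 adjusted over the list alone). The interferon response list had a camera adjusted p of 0.0139 (adjusted p = 0.718 with an estimated correlation). The leading genes were Ifi27l2a (2.10 ± 0.29, offset fit 1.37) and Gbp4 (1.35 ± 0.23, offset fit 1.24), and Oasl2 (−0.59 ± 0.18, offset fit −0.27, adjusted p = 0.230) fell. With the offsets 13 rose (camera adjusted p = 0.0177). The count of increases was 10 without control 1, 4 without KO 2 and 9 without KO 3, and that of decreases 1 without control 1, 4 without control 2 and 0 without KO 1 or KO 2. In the TNF and NF-κB list 9 of 22 rose, including Tnfrsf12a (1.60 ± 0.25, offset fit 1.76) and Cd40 (1.47 ± 0.31, offset fit 1.36). In it 4 fell, including Nfkb2 (−0.98 ± 0.21, offset fit −0.065, adjusted p = 0.746) (9 and 5 adjusted over the list alone). Its median was −0.044 and its mean 0.16, and the median turned to 0.34 with the offsets (camera adjusted p = 0.0732) and to 0.12 without control 2. Camera, whose direction was higher, made no call (adjusted p = 0.854). The increases there numbered 3 without control 1 or KO 3 and 2 without KO 2. Its decreases numbered 8 without control 2, 7 without control 3 and 2 without KO 2, so that without control 2 they outnumbered the increases, 8 to 7. In the antigen presentation list 4 of 13 rose, such as the class II gene H2-Aa (0.89 ± 0.22, offset fit 0.67). A further 5 fell, such as the peptide transporter Tap2 (−1.49 ± 0.22, offset fit −0.91) and the class I gene H2-K1 (−0.56 ± 0.16, offset fit −0.39, adjusted p = 0.0605) (5 and 5 adjusted over the list alone). The offset fit called 5 higher and 1 lower, and the decreases numbered 2 without control 1 or KO 3 and 1 without KO 1 or KO 2. Its increases numbered 2 without control 1 or KO 3 and 0 without KO 2. For this list camera made no call (adjusted p = 0.982; median 0.10 but −0.060 without control 2 and −0.020 without KO 2, mean 0.043, camera direction lower). Complement genes rose in 6 of 17 cases, such as Cfd (2.15 ± 0.77, offset fit 1.99, adjusted p = 0.0512) and Cfi (1.17 ± 0.20, offset fit 0.71), and fell in 2, Cfb (−0.78 ± 0.27, offset fit −0.75) the most (6 and 2 adjusted over the list alone). For the complement list camera gave an adjusted p of 0.122. The complement increases were 3 without KO 2 or KO 3, and the decreases 1 without control 1, KO 2 or KO 3. In this group the calls lost with a library left out, with the adjusted p, were those of Oasl2 (0.0871 without control 1, 0.0995 without KO 1 and 0.0719 without KO 2), H2-Aa (0.0539 without KO 2), H2-K1 (0.0722 without control 1, 0.0789 without KO 1, 0.0603 without KO 2 and 0.0574 without KO 3), Cfd (0.153 without control 1, 0.0568 without control 2, 0.0730 without KO 1 and 0.219 without KO 3) and Cfb (0.0716 without control 1, 0.136 without KO 2 and 0.133 without KO 3). Leaving out 1 library moved Cfd from 2.15 to 3.28 without control 3 and to 1.13 without KO 3. It moved Cfb from −0.78 to −1.17 without KO 1.

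Cell cycle genes had the lowest camera p of all lists with all 6 libraries. Without control 3 the ribosomal protein list ranked above them (camera adjusted p = 1.04e-09 against 1.65e-06). Of 36 tested, 26 rose and 1 fell (30 and 1 adjusted over the list alone), with a median of 1.40. The spindle checkpoint kinase Bub1 (3.34 ± 0.30, offset fit 2.79) and cyclin B1 Ccnb1 (3.02 ± 0.34, offset fit 2.68) followed Cdk1, and Cdk1 itself went from 1.52 ± 0.49 to 16.6 ± 5.4 CPM (SD). The exception was the replication licensing gene Mcm2 (−0.75 ± 0.17, offset fit −0.17, adjusted p = 0.313). Camera gave an adjusted p of 4.13e-09 (adjusted p = 0.617 with an estimated correlation) and 9.78e-13 with the offsets, where 30 members rose. In the tubular injury list 15 of 35 rose and 6 fell (16 and 6 adjusted over the list alone), with Havcr1, Ccl2 and the lipocalin Lcn2 (2.34 ± 0.37, offset fit 2.44) higher, and clusterin Clu (−1.51 ± 0.15, offset fit −1.12) the lowest. Camera made no call for it (adjusted p = 0.0599; 0.0483 without control 1 and 0.0150 without KO 1). The injury list had 3 without control 1, KO 2 or KO 3 as its count of decreases.

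Of 19 senescence and p53 genes, 6 rose, led by Eda2r (2.34 ± 0.30, offset fit 1.94) and Fas (1.12 ± 0.32, offset fit 0.49, adjusted p = 0.126). Among the same genes 4 fell, including Sesn2 (−0.91 ± 0.21, offset fit −0.26, adjusted p = 0.192) (6 and 4 adjusted over the list alone). Camera on the senescence and p53 list gave an adjusted p of 0.458. The offset fit left 3 higher and 1 lower. Senescence increases were 3 without KO 2, and decreases 2 without control 2, KO 1, KO 2 or KO 3. Among 18 apoptosis and necroptosis genes 5 rose, such as Mcl1 (0.76 ± 0.18, offset fit 0.64). Lower were 2, such as Tnfrsf1a (−0.45 ± 0.12, offset fit −0.24, adjusted p = 0.0939) (5 and 1 adjusted over the list alone). The apoptosis and necroptosis list had a camera adjusted p of 0.317. The increases numbered 3 without KO 2, and the decreases 0 without control 1, KO 1, KO 2 or KO 3. Fas and Tnfrsf1a lost their calls with a library left out, with the adjusted p of Fas (0.0663 without control 1 and 0.0724 without KO 2) and Tnfrsf1a (0.0605 without control 1, 0.0692 without KO 1, 0.0772 without KO 2 and 0.0658 without KO 3).

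**Figure D3:**
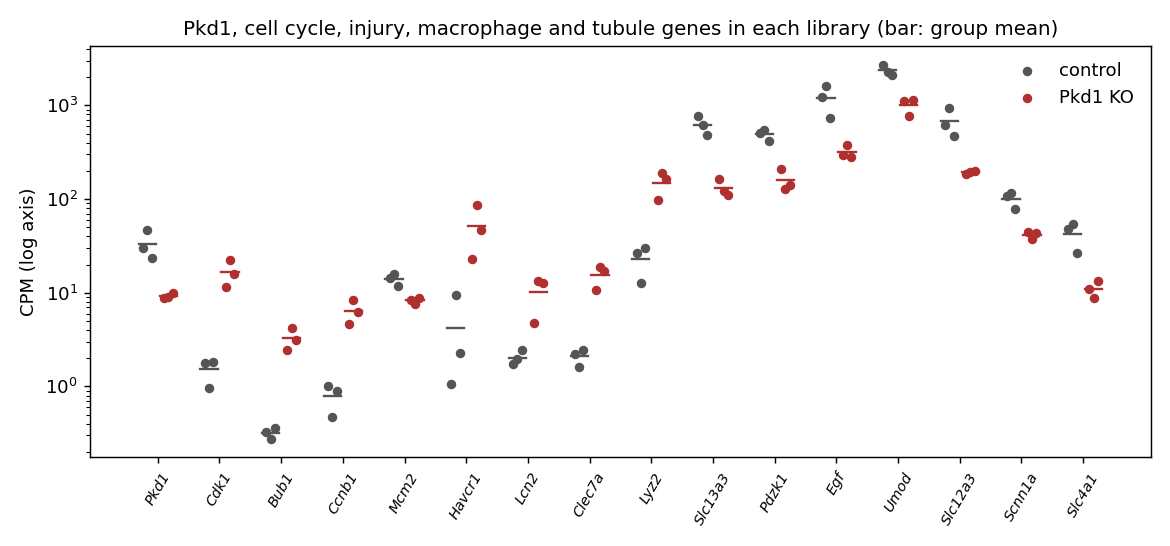
CPM (log axis) of Pkd1 and of cell cycle, injury, macrophage and tubule genes in each of the 3 control and 3 Pkd1 KO libraries, with a bar at each group's mean. Cdk1, Bub1, Ccnb1, Havcr1, Lcn2, Clec7a and Lyz2 lie higher in the Pkd1 KO libraries, and Pkd1, Mcm2 and the tubule genes on the right lie lower.

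Genes of the tubule segments fell more often than they rose. In the proximal tubule list 19 of 43 fell and 6 rose (19 and 6 adjusted over the list alone), with the dicarboxylate transporter Slc13a3 (−2.24 ± 0.23, offset fit −1.51) next after Slc7a8 and the brush border scaffold Pdzk1 (−1.62 ± 0.21, offset fit −1.62) also lower. For the proximal tubule list camera gave an adjusted p of 0.0245 (adjusted p = 0.642 with an estimated correlation). Kap (1.14 ± 0.27, offset fit 0.22, adjusted p = 0.405), an androgen-regulated protein, was the largest exception. Proximal tubule increases numbered 3 without control 1. The offset fit called 20 lower and 1 higher (camera adjusted p = 0.000419). Of 13 thick ascending limb genes 9 fell (10 adjusted over the list alone), led by Egf (−1.89 ± 0.28, offset fit −1.14) and uromodulin, Umod (−1.23 ± 0.20, offset fit −1.31), and 8 with the offsets. Camera on the thick ascending limb list gave an adjusted p of 0.00210 (adjusted p = 0.617 with an estimated correlation). In the distal convoluted and connecting tubule list 10 of 13 fell (10 adjusted over the list alone), among them the thiazide-sensitive cotransporter Slc12a3 (−1.81 ± 0.24, offset fit −0.74) and Slc8a1 (−1.71 ± 0.28, offset fit −1.46), while the calcium-binding S100g (0.87 ± 0.26, offset fit −0.035, adjusted p = 0.891) rose. The distal convoluted and connecting tubule list had a camera adjusted p of 0.00400 (adjusted p = 0.617 with an estimated correlation). The offset fit called 11 lower.

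Collecting duct genes moved the same way. Principal cell genes fell in 7 of 12 cases and rose in 1 (7 and 1 adjusted over the list alone), with the sodium channel subunits Scnn1a (−1.26 ± 0.17, offset fit −0.64) and Scnn1g (−0.74 ± 0.14, offset fit −0.89) lower and Tspan1 (0.78 ± 0.17, offset fit 0.45) higher. For the principal cell list camera gave an adjusted p of 0.0383 (adjusted p = 0.617 with an estimated correlation). Principal cell decreases numbered 3 without control 1, KO 1, KO 2 or KO 3, and the camera adjusted p 0.0502 without control 3 and 0.0686 without KO 1. Intercalated cell genes fell in 9 of 17 cases and rose in 2 (9 and 2 adjusted over the list alone). Camera on the intercalated cell list gave an adjusted p of 0.0383 (adjusted p = 0.617 with an estimated correlation, 0.0513 without control 1). The anion exchanger Slc4a1 (−1.96 ± 0.27, offset fit −1.34) and proton pump subunit Atp6v1b1 (−1.90 ± 0.25, offset fit −1.52) fell and Spink8 (1.24 ± 0.26, offset fit 0.45, adjusted p = 0.0645) rose. In the thin limb list 3 of 8 fell, such as Corin (−1.74 ± 0.32, offset fit −1.60). Thin limb genes that rose numbered 2, such as Bst1 (0.89 ± 0.27, offset fit 0.41, adjusted p = 0.170) (3 and 2 adjusted over the list alone). The thin limb list had a camera adjusted p of 0.476, and with the offsets 2 fell and 1 rose. Calls lost with a library left out, with the adjusted p, were those of S100g (0.0741 without control 1, 0.0706 without KO 1 and 0.0867 without KO 2) and Bst1 (0.0744 without control 1, 0.0904 without KO 2 and 0.0948 without KO 3). Thin limb increases thereby numbered 0 without control 1, KO 2 or KO 3 and 1 without KO 1.

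Podocyte and endothelial lists were called lower without the offsets only. Of 12 podocyte genes 8 fell (10 adjusted over the list alone), such as nephrin, Nphs1 (−1.46 ± 0.41, offset fit −0.46, adjusted p = 0.246), and Plce1 (−1.44 ± 0.34, offset fit −0.62, adjusted p = 0.0592). For the podocyte list camera gave an adjusted p of 0.0164 (adjusted p = 0.642 with an estimated correlation). With the offsets 3 fell and the list's call ended (camera adjusted p = 0.149). Of 16 endothelial genes 10 fell and 2 rose (10 and 2 adjusted over the list alone), such as Flt1 (−1.20 ± 0.17, offset fit −0.32, adjusted p = 0.0553), Cdh5 (−1.09 ± 0.20, offset fit −0.83) and, higher, Egfl7 (0.80 ± 0.15, offset fit 1.32). Camera on the endothelium list gave an adjusted p of 0.00714 (adjusted p = 0.617 with an estimated correlation). In the offset fit 3 fell and 1 rose (camera adjusted p = 0.169). The podocyte count was 3 without control 1, KO 1 or KO 3 and 5 without KO 2, and the endothelial one 6 without KO 2 or KO 3. Endothelial increases numbered 1 without control 1, KO 1, KO 2 or KO 3, and 1 urothelial gene was lower without KO 3. In edgeR's test 0 of 8 urothelial genes were called, 0 at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom (camera adjusted p = 0.914, direction lower; median 0.053, mean 0.052, median with the offsets −0.15). The most abundant were Psca (0.033 ± 0.58, adjusted p = 0.967) and Upk3b (0.49 ± 0.40, adjusted p = 0.326). Nphs1 lost its call with a library left out, at an adjusted p of 0.0579 without control 1, 0.0673 without KO 1, 0.0543 without KO 2 and 0.0573 without KO 3.

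Matrix and stromal genes went both ways, and the offsets turned the median of the matrix list. Of 41 extracellular matrix genes 16 fell and 9 rose (18 and 9 adjusted over the list alone), with no camera call (adjusted p = 0.130) and a median of −0.51. The basement membrane genes Col18a1 (−1.60 ± 0.22, offset fit −0.32, adjusted p = 0.0794) and Lamb1 (−1.56 ± 0.38, offset fit −0.59, adjusted p = 0.0759) fell, and the metalloproteinase inhibitor Timp1 (3.05 ± 0.56, offset fit 2.53) rose. With the offsets 13 rose and 1 fell, and the median was 0.18. Camera then called the list higher (adjusted p = 0.0202). The decreases numbered 9 without control 1 or KO 2, 4 without KO 1 and 10 without KO 3, the increases 5 without KO 3, and camera called the list lower at 0.0325 without control 3. Lamb1 moved from −1.56 to −0.95 without control 2. Of 19 fibroblast and myofibroblast genes 6 rose, such as decorin, Dcn (1.07 ± 0.25, offset fit 0.42, adjusted p = 0.108), and the collagen Col3a1 (0.97 ± 0.23, offset fit 1.80). A further 4 fell, the smooth muscle myosin Myh11 (−1.996 ± 0.63, offset fit −1.10, adjusted p = 0.11) the most (6 and 4 adjusted over the list alone). The fibroblast and myofibroblast list had a camera adjusted p of 0.854. With the offsets 7 rose and 1 fell. Increases there were 3 without KO 2 or KO 3, and decreases 2 without KO 1, KO 2 or KO 3. Myh11 moved from −1.996 to −0.91 without control 2, and its adjusted p was 0.101 without KO 1, 0.0860 without KO 2 and 0.0642 without KO 3.

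Wnt genes fell in 12 of 23 cases (12 adjusted over the list alone), such as Wnt11 (−3.69 ± 0.57, offset fit −3.09), a ligand of the ureteric bud tip, and the Wnt receptor ligase Znrf3 (−1.43 ± 0.27, offset fit −0.81). For the Wnt signalling list camera gave an adjusted p of 0.000788 (adjusted p = 0.617 with an estimated correlation). The offset fit kept the list's camera call (adjusted p = 0.0177) with 9 members lower. In the cilium and polycystic disease list 11 of 25 fell, Pkd1 and the transcription factor Glis3 (−1.87 ± 0.39, offset fit −1.17) the most. The intraflagellar transport gene Ift20 (1.06 ± 0.23, offset fit 0.53) rose (11 and 1 adjusted over the list alone). Camera on the cilium and polycystic disease list gave an adjusted p of 0.00775 (adjusted p = 0.617 with an estimated correlation). That call ended with the offsets (adjusted p = 0.169; 4 higher, 8 lower), and the decreases were 17 without control 3. Of 21 YAP and TAZ genes 8 fell, such as Ptpn14 (−1.59 ± 0.35, offset fit −0.47, adjusted p = 0.0774) and Arhgef17 (−1.54 ± 0.30, offset fit −0.14, adjusted p = 0.431). The cardiac ankyrin repeat gene Ankrd1 (1.75 ± 0.41, offset fit 1.46) rose (8 and 1 adjusted over the list alone). The YAP and TAZ list had a camera adjusted p of 0.0391 (adjusted p = 0.650 with an estimated correlation). This call ended with the offsets (adjusted p = 0.501; median 0.040 against −0.50) and at 0.0596 without control 1 and 0.0618 without KO 1. Of 19 cAMP signalling genes 8 fell, led by the adenylyl cyclase Adcy5 (−1.77 ± 0.29, offset fit −0.53) and Gnas (−1.69 ± 0.24, offset fit −0.37, adjusted p = 0.208), whose locus holds overlapping transcripts and is uncertain. In this list 3 rose, Crem (1.05 ± 0.28, offset fit 0.84) the most (8 and 3 adjusted over the list alone). For the cAMP signalling list camera gave an adjusted p of 0.122. With the offsets 3 fell. The increases numbered 1 without control 1 or KO 2 in the cAMP list and 2 without control 1 in the YAP and TAZ list. Glis3 moved from −1.87 to −1.21 without control 2, and Crem lost its call at an adjusted p of 0.0535 without control 1 and 0.0604 without KO 2.

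Most ribosomal protein genes rose. Of 42 tested, 33 rose (36 adjusted over the list alone), such as Rps24 (1.76 ± 0.32, offset fit 1.58) and Rps25 (1.68 ± 0.30, offset fit 1.58). With the offsets 30 rose. Camera on the cytosolic ribosomal proteins list gave an adjusted p of 1.15e-07 (adjusted p = 0.642 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain, and the number was 20 without control 1 or KO 2. Oxidative phosphorylation genes split, 23 of 44 higher, such as Cox7b (1.46 ± 0.28, offset fit 0.61) and Ndufa4 (1.46 ± 0.29, offset fit 0.58). Those lower numbered 5, such as Sdha (−1.06 ± 0.22, offset fit −1.09) (24 and 5 adjusted over the list alone). The oxidative phosphorylation list had a camera adjusted p of 0.0236 (adjusted p = 0.783 with an estimated correlation). The offset fit called 9 higher and ended the list's call (adjusted p = 0.517), as did single left-out libraries (0.0972 without control 2 and 0.0516 without KO 1). The increases were 7 without control 1, 12 without KO 1, 5 without KO 2 and 15 without KO 3. The decreases were 2 without control 1, KO 2 or KO 3 and 9 without control 2. Of 11 mitochondrially encoded genes 3 rose and 2 fell (3 and 2 adjusted over the list alone). For the mitochondrially encoded list camera gave an adjusted p of 0.671. mt-Co3 (2.05 ± 0.28, offset fit 1.03) and mt-Co2 (1.76 ± 0.31, offset fit 0.68, adjusted p = 0.149), at 1.58 and 1.19 CPM in controls, have near-identical nuclear copies. In turn mt-Nd5 (−1.11 ± 0.22, offset fit −2.20) and mt-Nd6 overlap on opposite strands, so all of these are uncertain. With the offsets 7 fell and camera called the list lower (adjusted p = 0.00407).

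In the fatty acid oxidation list 14 of 31 fell (14 adjusted over the list alone), such as the ω-hydroxylases Cyp4a10 (−1.51 ± 0.25, offset fit −1.96) and Cyp4a14 (−1.49 ± 0.51, offset fit −1.92), close copies whose counts are uncertain. The carnitine carrier Slc25a20 (0.72 ± 0.20, offset fit 0.76) rose. Camera on the fatty acid oxidation list gave an adjusted p of 0.0364 (adjusted p = 0.689 with an estimated correlation). The list had 9 without control 1 or KO 2, and its camera adjusted p was 0.0529 without control 1, 0.124 without control 3 and 0.0525 without KO 3, against 0.00407 with the offsets. Among gluconeogenic and amino acid genes 10 of 23 fell, such as Gldc (−1.27 ± 0.21, offset fit −0.62) and Prodh2 (−1.13 ± 0.15, offset fit −0.78). In contrast Bhmt (0.89 ± 0.21, offset fit 0.65) rose (10 and 1 adjusted over the list alone). The gluconeogenic and amino acid list had a camera adjusted p of 0.0305 (adjusted p = 0.642 with an estimated correlation, 0.0542 without control 1). That count was 6 without control 1 and 5 without KO 2 or KO 3. Tricarboxylic acid cycle genes fell in 6 of 18 cases, Ogdh (−1.37 ± 0.22, offset fit −0.89) the most (6 adjusted over the list alone), with no camera call (adjusted p = 0.0932; 0.0256 without control 2; 0.0126 with the offsets). Glycolysis genes fell in 12 of 20 cases, such as Hk1 (−1.63 ± 0.26, offset fit −0.52) and Pfkl (−1.55 ± 0.21, offset fit −0.56). The neuronal enolase gene Eno2 (0.80 ± 0.27, offset fit 1.36) rose (12 and 1 adjusted over the list alone). For the glycolysis list camera gave an adjusted p of 0.0297 (adjusted p = 0.617 with an estimated correlation). With the offsets 4 fell and camera made no call (adjusted p = 0.217). Calls lost with a library left out, with the adjusted p, were those of Cyp4a14 (0.155 without control 1, 0.132 without KO 1, 0.0947 without KO 2 and 0.0881 without KO 3), Slc25a20 (0.0640 without control 1, 0.0677 without KO 1, 0.0648 without KO 2 and 0.0509 without KO 3) and Eno2 (0.0670 without control 1, 0.0985 without control 3, 0.133 without KO 2 and 0.120 without KO 3). Without control 3, 5 fatty acid oxidation genes and 2 tricarboxylic acid cycle genes were higher.

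Of 16 NRF2 antioxidant genes 8 fell, led by the glutathione transferases Gsta2 (−1.39 ± 0.17, offset fit −2.12) and Gstm1 (−1.20 ± 0.16, offset fit −1.51), which have close copies and are uncertain. NRF2 genes that rose numbered 2, including Nqo1 (0.52 ± 0.17, offset fit −0.093, adjusted p = 0.544) (10 and 2 adjusted over the list alone). Camera on the NRF2 antioxidant list gave an adjusted p of 0.0297 (adjusted p = 0.617 with an estimated correlation, 0.0524 without control 3; 0.00324 with the offsets). The decreases were 5 without KO 2 or KO 3, and the increases 0 without control 1, KO 2 or KO 3 and 1 without control 2 or KO 1. Cholesterol synthesis genes fell in 7 of 22 cases, such as the sterol demethylase Cyp51 (−0.76 ± 0.16, offset fit −0.91). The sterol-responsive transcription factor Srebf2 (−0.78 ± 0.19, offset fit 0.31) fell too, and was called higher with the offsets. The isomerase gene Idi1 (0.49 ± 0.17, offset fit −0.093, adjusted p = 0.577) rose (7 and 0 adjusted over the list alone). The cholesterol synthesis list had a camera adjusted p of 0.0459 (adjusted p = 0.617 with an estimated correlation, 0.0596 without control 1 and 0.0539 without KO 2). With the offsets 4 fell (camera adjusted p = 0.0732). Of 11 heat shock genes 7 fell and Hspe1 (1.15 ± 0.36, offset fit 0.52, adjusted p = 0.144) rose (8 and 1 adjusted over the list alone), the near-identical pair Hspa1a (−1.52 ± 0.37, offset fit −0.97, adjusted p = 0.0536) and Hspa1b (−1.30 ± 0.27, offset fit −0.87) being uncertain. For the heat shock list camera gave an adjusted p of 0.0383 (adjusted p = 0.642 with an estimated correlation, 0.0515 without control 1 and 0.11 without control 3). Of 11 renin-angiotensin and vasoactive genes 4 fell, such as Ace (−1.93 ± 0.19, offset fit −1.23) and Nos3 (−1.28 ± 0.20, offset fit −0.56) (4 adjusted over the list alone), and 6 with the offsets, where camera called the list (adjusted p = 0.00850). Without control 2, 1 gene was higher. Without the offsets camera on the renin angiotensin and vasoactive list gave an adjusted p of 0.0844. Among 21 MYC and mTORC1 genes 11 rose, such as Mthfd2 (0.9998 ± 0.24, offset fit 0.96) and Psat1 (0.93 ± 0.32, offset fit 0.92). Those that fell numbered 5, such as nucleolin, Ncl (−1.60 ± 0.29, offset fit −1.47) (11 and 5 adjusted over the list alone). The MYC and mTORC1 list had a camera adjusted p of 0.165. The increases were 5 without control 1 or KO 2, 6 without KO 1 and 4 without KO 3, and the decreases 3 without control 1 or KO 2. Calls lost with a library left out, with the adjusted p, were those of Nqo1 (0.126 without control 1, 0.0518 without control 2, 0.103 without KO 1, 0.108 without KO 2 and 0.0745 without KO 3), Srebf2 (0.0517 without KO 2), Idi1 (0.131 without control 1, 0.0777 without control 2, 0.137 without KO 1, 0.122 without KO 2 and 0.0899 without KO 3), Hspe1 (0.103 without control 1, 0.0717 without KO 1, 0.0898 without KO 2 and 0.0547 without KO 3) and Psat1 (0.115 without control 1, 0.0902 without KO 1, 0.119 without KO 2 and 0.0764 without KO 3). Values moved from 0.93 to 0.59 without control 2 for Psat1, 0.49 to 0.32 without control 2 for Idi1 and −1.52 to −0.998 without control 1 for Hspa1a.

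The remaining lists had no camera call. In the hypoxia list 4 of 17 rose, Bnip3 (1.28 ± 0.26, offset fit 0.54) the most. Hypoxia genes that fell numbered 5, such as Egln1 (−0.92 ± 0.15, offset fit −0.46) and P4ha2 (−0.85 ± 0.17, offset fit −0.35, adjusted p = 0.190) (6 and 5 adjusted over the list alone). For the hypoxia response list camera gave an adjusted p of 0.748. In the unfolded protein response list 3 of 18 rose, Atf3 (1.96 ± 0.33, offset fit 1.80) the most. It had 4 that fell, such as Edem1 (−1.02 ± 0.16, offset fit −0.94) and Hsp90b1 (−0.91 ± 0.19, offset fit −1.41) (3 and 4 adjusted over the list alone). Camera on the unfolded protein response list gave an adjusted p of 0.565 (0.0350 without control 2). Hypoxia decreases were 2 without KO 2 and 3 without KO 3, and hypoxia increases 2 without control 1, KO 2 or KO 3. Unfolded protein decreases were 2 without control 1, KO 1, KO 2 or KO 3 and 11 without control 2, and the increases 1 without control 1, KO 1, KO 2 or KO 3. Of 18 immediate early genes 3 rose, including Egr2 (1.65 ± 0.59, offset fit 1.71), and Jund (−0.84 ± 0.20, offset fit −0.18, adjusted p = 0.418) fell (2 and 1 adjusted over the list alone). The immediate early list had a camera adjusted p of 0.854 (median −0.17, 0.15 with the offsets, mean −0.014, camera direction higher). Camera called them higher at 0.0483 without control 1, where the median was 0.43, and the increases numbered 7 without control 1. The decreases there numbered 4 without control 2, 6 without control 3 and 0 without KO 2, and without control 3 the median was −0.50 with 2 genes higher. Of 17 circadian genes 3 fell, led by Nr1d1 (−1.55 ± 0.32, offset fit −1.14) and Dbp (−1.31 ± 0.47, offset fit −0.56, adjusted p = 0.339). The Nr1d1 relative Nr1d2 (0.98 ± 0.25, offset fit 0.63) rose (1 and 1 adjusted over the list alone), and the decreases were 5 without control 2, 7 without control 3 and 1 without KO 1 or KO 3. For the circadian list camera gave an adjusted p of 0.197. Replication-dependent histone genes, which largely lack poly-A tails, had 1 call among 6, Hist1h1e (−1.19 ± 0.39, offset fit −1.45), lost when adjusted over the list alone (camera adjusted p = 0.905). Without control 3, 2 histone genes were higher, and without control 2, 2 were lower. The calls of this paragraph lost with a library left out, with the adjusted p, were those of Egr2 (0.0718 without control 2, 0.0902 without control 3, 0.0699 without KO 1, 0.178 without KO 2 and 0.0714 without KO 3), Jund (0.0518 without KO 2), Dbp (0.1 without control 2, 0.126 without KO 1, 0.125 without KO 2 and 0.106 without KO 3), Nr1d2 (0.0537 without control 1 and 0.0562 without KO 2) and Hist1h1e (0.0699 without control 1, 0.0708 without control 3, 0.0738 without KO 1, 0.114 without KO 2 and 0.0850 without KO 3). Egr2 moved from 1.65 to 2.79 without control 1, Dbp from −1.31 to −0.67 without control 2 and Hist1h1e from −1.19 to −0.77 without control 3.

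Markers of other tissues were also counted. Of 9 adipose genes 3 rose, Adipoq (2.20 ± 0.77, offset fit 1.69, adjusted p = 0.0815), Fabp4 (1.49 ± 0.26, offset fit 1.10) and Cfd (1 adjusted over the list alone), and the count was 1 without control 1, KO 1 or KO 3, 7 without control 3 and 6 without KO 2. Camera on the adipose list gave an adjusted p of 0.108 (0.0489 without control 3 and 0.0246 without KO 2). KO 3 was the highest library for Adipoq (9.98 CPM) and Cfd (46.6 CPM), which is also in the complement list. Of 6 hemoglobin and red cell genes Slc25a37 (−0.42 ± 0.15, offset fit −0.23, adjusted p = 0.145) fell, a call lost when adjusted over the list alone (camera adjusted p = 0.422, 0.0342 without KO 3). Without KO 3, 3 of these and 1 adipose gene were lower. The skeletal muscle list had 3 tested genes, of which Tnni2 (2.52 ± 0.58, offset fit 2.38), named after its value was seen, rose (1 adjusted over the list alone), beside Mylpf (0.20 ± 0.28, adjusted p = 0.587) and Actn3 (−0.77 ± 0.39, adjusted p = 0.132). Tnni2 lay below the mean log2 CPM of 0 that the rule for named list members required. Of 2 tested adrenal genes, Star (−0.33 ± 0.29, adjusted p = 0.375) and Akr1b7 (0.093 ± 0.25, adjusted p = 0.774), edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. Of 4 tested Y-linked genes Uty (0.67 ± 0.15, offset fit 0.15, adjusted p = 0.368) rose (1 adjusted over the list alone). Slc25a37 and Adipoq lost their calls with a library left out, with the adjusted p of Slc25a37 (0.0991 without control 1, 0.0568 without control 2, 0.102 without KO 1, 0.119 without KO 2 and 0.156 without KO 3) and Adipoq (0.140 without control 1, 0.0790 without KO 1 and 0.175 without KO 3). The Adipoq value moved from 2.20 to 3.35 without control 3 and to 1.40 without KO 3.

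Across lists, camera called 25 of 49 with at least 5 tested members (9 higher, 16 lower) and fry 23. With a correlation estimated for each list instead of the preset 0.01, camera called 0, with 1 list at an unadjusted p under 0.05, and the lowest adjusted p was 0.617. With the offsets camera called 22 lists, and 18 of them had also been called, in the same direction, without the offsets.

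**Figure D4:**
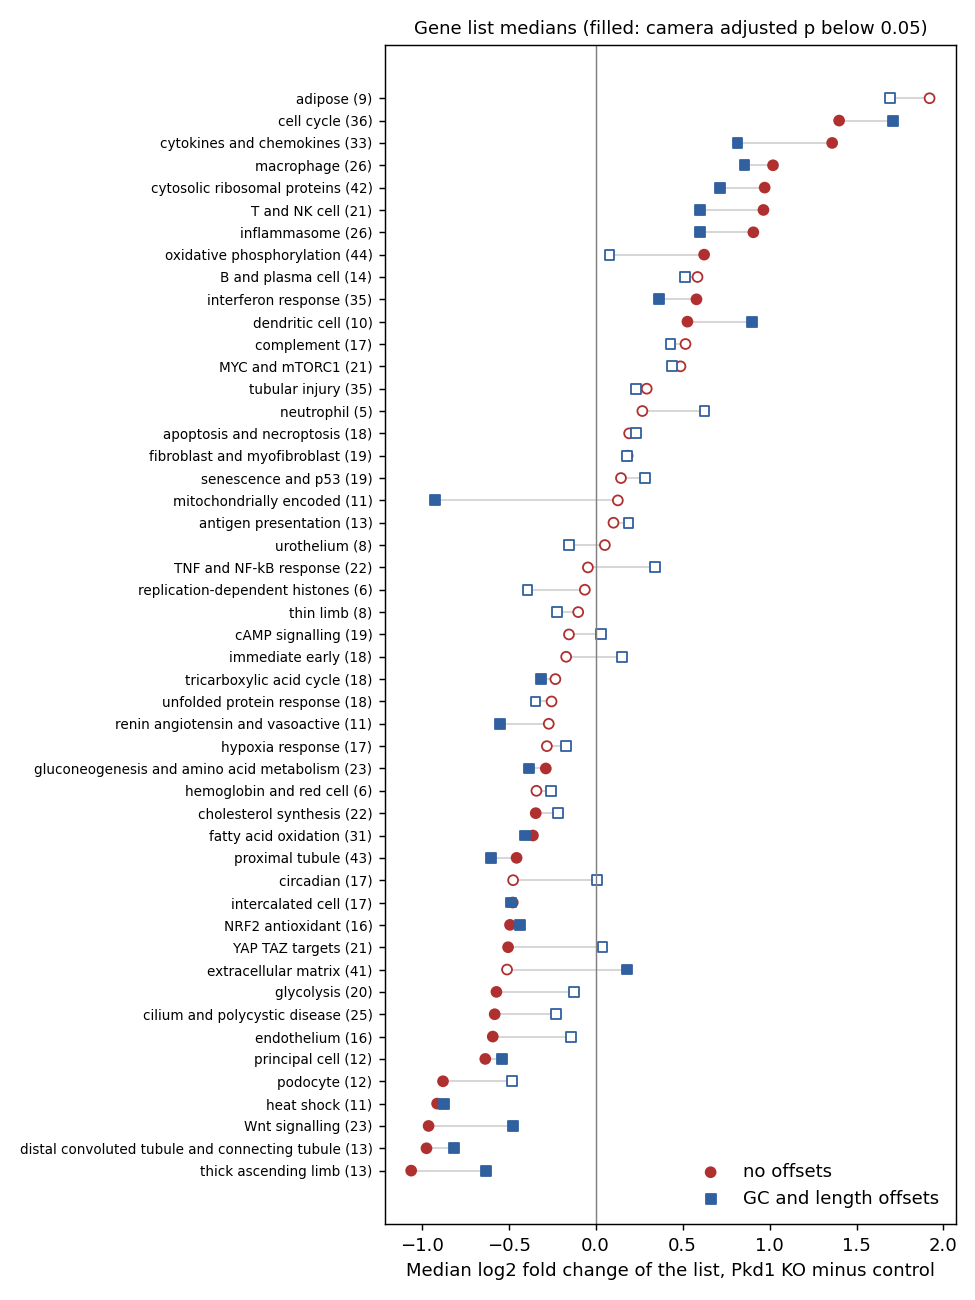
Median log2 fold change (Pkd1 KO minus control) of each list with at least 5 tested members (number in parentheses), without offsets (circles) and with GC and length offsets (squares), filled where camera's adjusted p with the preset correlation was below 0.05. Cell cycle moved from 1.40 to 1.71 with the offsets, and extracellular matrix from −0.51 to 0.18.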

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

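All tests in this part were chosen after the result they bear on was seen. Reads mapping to more than 1 place, which enter no gene count, made up 12.2%, 13.4% and 12.5% of reads in KO 1, KO 2 and KO 3. The controls had 9.49%, 9% and 10.6%, so every Pkd1 KO library lay above the highest control. Unmapped reads were lower in KO 1, KO 2 and KO 3, at 4.21%, 3.9% and 3.95%, against 5.07%, 5.16% and 4.59% in the controls. Genes with a count numbered 26601, 27702 and 27611, against 24281, 25752 and 24496. The shares of reads outside genes, ambiguous reads and mitochondrial counts overlapped between the groups.

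Long and GC-rich genes, Pkd1 among them, were lower in the Pkd1 KO libraries. A GC content and length bias between libraries is a candidate explanation. The difference between the Pkd1 KO mean and control 1 followed that between control 3 and control 2, libraries of 1 genotype (Spearman's rho 0.547 across genes, which are not independent replicates). This value uses neither GC content nor length, so it shows a shared axis and does not single out this bias. Control 3 minus control 2 had a rho of −0.384 with length and −0.183 with GC content. Of the 200 nearest genes in length, GC content and expression, 12.5% fell further than Pkd1, so the bias as the whole of the lower Pkd1 count is not excluded. Those neighbours, of which 178 were called lower, may include genes changed for other reasons, so they cannot establish it either. In edgeR's test Pkd1 was still called lower with a finer loess (−0.46, adjusted p = 0.016) and with the offsets without control 2 (−0.45, adjusted p = 0.0161). A difference between sequencing projects cannot be told apart from genotype, as 0 projects held both groups. Loss of Pkd1 in recombined cells, which the design names, stays open and was not tested by these values.

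Most tested genes of the inflammasome, macrophage and cell cycle lists were called higher in the Pkd1 KO libraries. The same bias is argued against as the whole cause: among 10000 random lists matched in length, GC content and expression, the medians of these lists stood at the percentiles 99.99, 100 and 100 (medians 0.91, 1.02 and 1.40, against random medians of 0.24, 0.31 and 0.04). Each random member was drawn separately, so the random lists lack the shared movement of related genes. The percentiles may therefore overstate the contrast, and they do not measure the spread between kidneys. A lower share of tubule cells alone would raise the genes of every other cell type alike. With the offsets, however, the macrophage median exceeded the endothelial one by 0.996 (95% bootstrap interval 0.676 to 1.54) and the podocyte one by 1.33 (0.769 to 1.89). These intervals resample the genes of each list, which are not independent replicates, and not the kidneys. The comparison takes endothelial and podocyte content as unchanged, so a lower tubule share beside other shifts in cell content is not excluded. A difference between the sequencing projects stays open, as does a change in the kidneys themselves, which was not tested apart from it.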

How the results depend on the processing

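The finer loess and the offsets without control 2 were chosen after seeing the data. Pkd1 kept its direction in every alternative, from −2.09 to −1.57 with 1 library left out, but lost its call with the offsets (−0.34, adjusted p = 0.0644) and with block and offsets (−0.33, adjusted p = 0.0929), over a range of adjusted p from 7.91e-11 in DESeq2's test. It was called with a finer loess (−0.46, adjusted p = 0.016) and with the offsets without control 2 (−0.45, adjusted p = 0.0161). With 1 library left out the count of changed genes ran from 5071 to 10318, those higher from 2340 to 4877, those lower from 2731 to 5441, those changed at least 2-fold from 3073 to 5546, and called lists from 21 to 26. Fewer samples enter these fits. Genes changed at least 2-fold numbered 1803 with the offsets, 1685 with block and offsets, 1453 with the offsets without control 2 and 1792 with a finer loess. Block and offsets together gave 5401 changed genes, 2719 higher and 2682 lower. Called lists numbered 14 with the stricter filter, 16 and 14 with the first and second strand column, and 0 in camera with an estimated correlation, where 1 list had an unadjusted p under 0.05. The calls lost with the filter (11) and with the first (9) and second (11) strand column are not marked in the list results above. The sample numbers showed no sign of pairing the kidneys, though these values cannot exclude a pairing. The deviations of same-numbered samples correlated at 0.0383, −0.0843 and −0.0291, and not every sample correlated best with its own number. The replicate block gave 7397 changed genes, 27 lists and −1.79 for Pkd1. Genes that changed sign, and medians of lists that did so and that camera called in at least 1 of the fits compared, were, with GC and length offsets, Pkd2 0.043, Txnip −0.060, S100g −0.035, Psca −0.23, Srebf2 0.31, Idi1 −0.093, Nqo1 −0.093, Akr1b7 −0.52, Mylpf −0.29, the extracellular matrix list 0.18, the YAP TAZ targets list 0.040 and the mitochondrially encoded list −0.92; with block and offsets, Pkd2 0.051, Txnip −0.039, S100g −0.012, Psca −0.44, Srebf2 0.31, Idi1 −0.091, Nqo1 −0.093, Akr1b7 −0.52, Mylpf −0.31, the extracellular matrix list 0.17, the YAP TAZ targets list 0.052 and the mitochondrially encoded list −0.91; with the offsets without control 2, Pkd2 0.16, Txnip −0.23, Nfkb2 0.0047, S100g −0.22, Psca −0.25, Srebf2 0.32, Idi1 −0.17, Nqo1 −0.14, Akr1b7 −0.46, Mylpf −0.25, the extracellular matrix list 0.24, the oxidative phosphorylation list −0.053 and the mitochondrially encoded list −0.88; and with a finer loess, Pkd2 0.061, Txnip −0.052, Psca −0.26, Srebf2 0.30, Idi1 −0.11, Nqo1 −0.11, Akr1b7 −0.55, Mylpf −0.31, the extracellular matrix list 0.18, the YAP TAZ targets list 0.051 and the mitochondrially encoded list −0.82. Upper-quartile scaling turned Nlrc4 0.073, limma-voom Psca −0.090, the replicate block Psca −0.13, the first strand column P2rx7 −0.054, the second strand column Mmp9 −0.0026, and the second run of control 1 alone Nlrc4 0.0027 and Psca −0.012. With 1 library left out the range crossed 0 for P2rx7 (−0.031 to 0.15), Psca (−0.95 to 0.55), Txnip (−0.11 to 0.35), Star (−0.56 to 0.048), Nlrc4 (−0.30 to 0.20), Akr1b7 (−0.019 to 0.21), Upk3b (−0.081 to 0.78) and for the medians of the lists immediate early (−0.50 to 0.43), TNF and NF-κB (−0.19 to 0.12), antigen presentation (−0.060 to 0.26), thin limb (−0.93 to 0.13), urothelium (−0.28 to 0.47), hemoglobin and red cell (−1.29 to 0.15), fibroblast and myofibroblast (−0.0085 to 0.33), histones (−0.16 to 0.048) and adrenal (−0.29 to 0.042). Medians of lists without a camera call in either fit turned with the offsets to 0.34 for TNF and NF-κB, 0.15 for immediate early, 0.030 for cAMP, 0.0091 for circadian, −0.15 for urothelium, −0.29 for skeletal muscle and −0.19 for Y-linked genes. Other settings turned the sign of such medians too. Upper-quartile scaling did so for TNF and NF-κB, thin limb, cAMP, adrenal, immediate early and histones, limma-voom and the replicate block for urothelium and immediate early, the stricter filter for histones and thinned counts for skeletal muscle. Both strand columns did so for TNF and NF-κB, adrenal and skeletal muscle, and the second also for neutrophil and immediate early. Of the genes that changed sign S100g, Idi1, Nqo1, Nfkb2 and Srebf2 were called without the offsets. The cause was not tested for any of them. Of 173 called genes named besides Pkd1, 41 lost the call with some library left out, 58 with an offset setting and 20 with another setting. Depth was 45020173 to 62983791 gene counts. The simulation recovered 6 of 50 genes changed 1.5-fold. It changed a small share of genes, whereas 46.9% were called in the data, so its adjusted threshold was stricter. Its recovery therefore does not measure the power of the real test, and statements on small changes of uncalled genes stay limited.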

Other observations

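The genes of the first paragraph and the adipose and run tests were chosen after their values were seen, and the counts of other splits were planned. Some genes outside the fixed lists were called in both fits and changed at least 2-fold in each. Anln (2.35 ± 0.25, offset fit 2.56), the cytokinesis scaffold anillin, rose from 1.69 ± 0.36 to 8.59 ± 2.2 CPM (SD, n = 3), and Racgap1 (2.17 ± 0.18, offset fit 2.32), which acts at the central spindle, from 1.97 ± 0.058 to 8.91 ± 1.0. Also higher were Rnase4 (2.86 ± 0.70, offset fit 2.29), from 51.8 ± 39 to 375 ± 143 CPM, and Serpina10 (2.74 ± 0.67, offset fit 2.46), from 1.44 ± 1.5 to 9.73 ± 5.2, with wide spreads, and the atypical cadherin Fat2 (1.33 ± 0.24, offset fit 2.27). Among the decreases were the calcium-sensing receptor Casr (−2.40 ± 0.29, offset fit −1.96), from 47.4 ± 19 to 8.996 ± 1.5 CPM, the organic anion transporter Slc22a26 (−1.42 ± 0.25, offset fit −2.04), from 49.3 ± 17 to 18.4 ± 2.3, and Malrd1 (−2.10 ± 0.29, offset fit −2.09), Muc20 (−2.18 ± 0.50, offset fit −2.04) and Hmgn5 (−1.23 ± 0.29, offset fit −2.20).

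Adipose genes varied together between libraries within both groups. The mean pairwise correlation of the within-group deviations of the 9 tested genes was 0.813, at percentile 100 of 10000 random lists matched in length, GC content and expression (random median 0.022). Fat carried over with some kidneys is a candidate explanation, as a hypothesis. KO 3 held the most Ucp1 (14.7 CPM, against 0 to 2.83 elsewhere) and Cfd (46.6, against 1.94 to 15.3), while Fabp4, which endothelium also expresses, was 141, 162 and 177 CPM in the Pkd1 KO libraries and 50.2, 39.1 and 81.8 in controls. Car3 was 7.86, 2.62 and 15.4 CPM in Pkd1 KO libraries and 20.0, 11.9 and 18.4 in controls.

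The 2 runs of control 1 differed along GC content. Over 12722 genes the log2 ratio of run 2 to run 1 had a Spearman's rho of 0.515 with GC content and −0.169 with length, across genes. Its median went from −0.11 in the eighth with the lowest GC content to 0.14 in that with the highest. Between control 3 and control 2 the rho was −0.183 with GC content and −0.384 with length, and for Pkd1 KO against control it was −0.395 and −0.387.

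The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. In 1 of the 10, the real split, 8579 genes changed, against a highest other of 1. For genes higher (4148), lower (4431) and changed at least 2-fold (4045) the real split was again the 1 with the most, and the highest other was 1 each, taking the larger of either direction since other splits have none. The real split called 25 lists and the highest other 18, and every other split called at least 10 with camera's preset correlation. Each other split sets 2 libraries of a genotype against 1, so part of the group difference remains in it. The rest enters the spread within its groups, which leaves few gene calls in any such split, whatever caused the group difference. The contrast in gene counts is therefore no evidence on the cause, and no test here separates it from another structure of the samples.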
